A study of Arabidopsis thaliana with 8 samples.

How the data were processed

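Total RNA from all tissues of Arabidopsis thaliana plants was hybridised to 8 Affymetrix ATH1 arrays, a 1-colour array on which each probe set summarises several short probes for a transcript. Per the labels, 4 arrays carry RNA of a Landsberg erecta (Ler) line with an extra copy of the chalcone synthase gene CHS that silences the resident gene, called the silenced parent here. The other 4 carry RNA of 15B, a mutant of that line obtained with ethyl methanesulfonate. The series title ties the work to hog1, and no label states the gene altered in 15B, so the groups are named by line. Per the labels, plants grew at 22 degrees C with 18 h light on agar (0.7%) with 1% sucrose after 3 days at 4 degrees C, and were at growth stage 1.04. The design text gives 10 pooled plants and 4 biological replicates.

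The deposited values are intensity values on a linear scale, 1 per probe set and array, for 22810 probe sets. The 2%-trimmed mean of each deposited array lay at 100.0, so the arrays had been brought to a common scale before deposit. That step removes any difference in total signal between arrays, and every change below is relative to the bulk of the probe sets. The software that summarised the probes and its background correction are not given in the sources used here. Values per probe were not used here, so probe sequence differences between the lines could not be examined. All columns of the table were mapped to an array.

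The 64 control probe sets were left out, which kept 22746. Values were transformed as log2(value + 10), with no further scaling. A fold change on this scale understates the change of a dim probe set. Probe sets with a mean over the 8 arrays under 30.0 signal units, 30% of the trimmed mean, were not tested. This left 13820 tested probe sets and 8926 below the filter. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Below, adjusted p stands for this value unless another test is named. Values are given as mean ± SD of the linear signal over 4 arrays per group, and fold changes as 15B minus silenced parent with their standard error (SE). The number of arrays limits the precision.

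Probe sets were named from the platform annotation of 2016 and updated through Entrez gene numbers to the RefSeq gene table of the assembly TAIR10.1. In this annotation 13513 probe sets name 1 gene, 503 name several and 8730 are unnamed. Of those with 1 gene, 13436 were found in the RefSeq table. Probe sets naming several genes were left unnamed. The planned comparisons of CHS itself and of SAHH1 (HOG1) were not analysed here, since no probe set was named for either. Positions from TAIR10.1 served only to place genes in gene order and to tell which lie around the centromeres (13367 probe sets placed). The suffixes of probe set names separate those designed for 1 transcript (_at) from those whose probes several sequences share (_s_at and _x_at).

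Choices made before the data were examined were the fit, the filter, 22 gene lists and the rule for named genes. Named are the 12 largest rises and the 12 largest falls past the threshold whose groups did not overlap and whose probe set names 1 gene. From each list up to 4 members past the threshold are named, or up to 2 members with the smallest p where none passed. Lists with at least 5 tested members were tested with limma's camera (correlation 0.01). Only 43 of the 333 listed loci had a named probe set, and 2 lists reached that size. Classes of loci were compared with Fisher's exact test, two-sided, which counts probe sets as independent. A planned class of transposable elements, found by words in the annotation, matched 1 probe set, which was below the filter. Loci with the RefSeq biotype pseudogene were used in its place, a choice made after seeing the data, and this biotype does not separate transposon genes from other pseudogenes. Families formed from gene symbols (20 sets), the 8 largest rises of protein-coding genes and the gene-order tests were also added after seeing the data.

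The arrays were checked for duplicates, and no pair shared more than 0.958% of its values. The limma steps were tested on simulated data for this comparison with 13820 probe sets. Of planted changes of 0.5 on the log2 scale, 26 of 50 were recovered. All 50 were recovered at each of 1, 2 and 4. Of 184 calls 8 were false (4.35%), and data without planted changes gave 0 calls. The simulated noise was normal and independent between probe sets and arrays, with no array effect. These rates thus check the steps and are not the error rates of the real calls. Alternatives were quantile normalization, median centring, pseudocounts of 1 and 30, no filter, a filter of 60.0, eBayes without the trend or with robust = TRUE, array weights, stricter thresholds and leaving out each array. Further ones were the replicate number as a block, only probe sets naming 1 gene, an estimated correlation or fry for lists, and only _at probe sets, for the pseudogene class also with no filter.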

Results

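Transcript levels were measured on 8 arrays, 4 of the silenced parent line and 4 of the mutant 15B, in a series whose title concerns genes affected when hog1 eases CHS silencing. Signals of the arrays correlated more closely within groups (r from 0.972 to 0.984 over 12 pairs) than between them (0.934 to 0.948 over 16 pairs), across probe sets, which are not independent replicates. The first principal component held 56.1% of the variance and separated the groups. Scanner background lay between 77.6 and 101 on 7 arrays and at 198 on replicate 4 of the silenced parent. The 3' to 5' signal ratio of actin, a measure of RNA integrity, was 6.61 ± 1.43 in the silenced parent and 5.24 ± 0.954 in 15B (SD, n = 4, exact permutation p = 0.143, adjusted over 9 array measures 0.429). Mean ratios of GAPDH (1.94 and 1.72) and ubiquitin (3.50 and 3.07) were also higher in the silenced parent (exact permutation p = 0.343 and 0.143). A difference in RNA quality between the groups is thus neither shown nor excluded.

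In 15B, signals of loci annotated as pseudogenes rose in 84 of 128 tested probe sets, and in 160 of 923 with no filter. This biotype holds the 3 listed transposon loci AT2G04770, AT4G08680 and AT2G10410. All 12 of the largest rises belonged to it. Among them AT2G13160, measured by an _x_at probe set whose probes several sequences share, went from 8.38 ± 4.50 to 3087 ± 261 (SD, n = 4). QQS, an orphan gene that affects starch content, and 3 of 7 tested flavonoid synthesis genes also rose, although the flavonoid list as a whole lost its call at camera adjusted p = 0.0918 with an estimated correlation. Among falls, AT1G66100, which encodes a thionin, dropped from 285 ± 94.1 to 7.23 ± 4.22, and the cold-induced genes COR47 and COR15A were lower.

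Of 13820 tested probe sets, 920 changed (limma, Benjamini-Hochberg), 431 higher and 489 lower in 15B. Rises were larger, since 156 of them and 35 of the falls reached 2-fold. The groups did not overlap for 1885 probe sets (13.6%), against 2.86% by chance, and 2970 had an unadjusted p under the threshold. More were higher than lower with median centring (439 and 405), with no filter (464 and 366) and without replicate 2 (350 and 288) or 3 (291 and 232) of the silenced parent or replicate 4 of 15B (327 and 318). The total was 523 without replicate 3 of the silenced parent and 588 without replicate 2 of 15B. The lower calls numbered 288 and 232 without replicates 2 and 3 of the silenced parent, and 296, 315 and 318 without replicates 2, 3 and 4 of 15B.

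**Figure D1:**
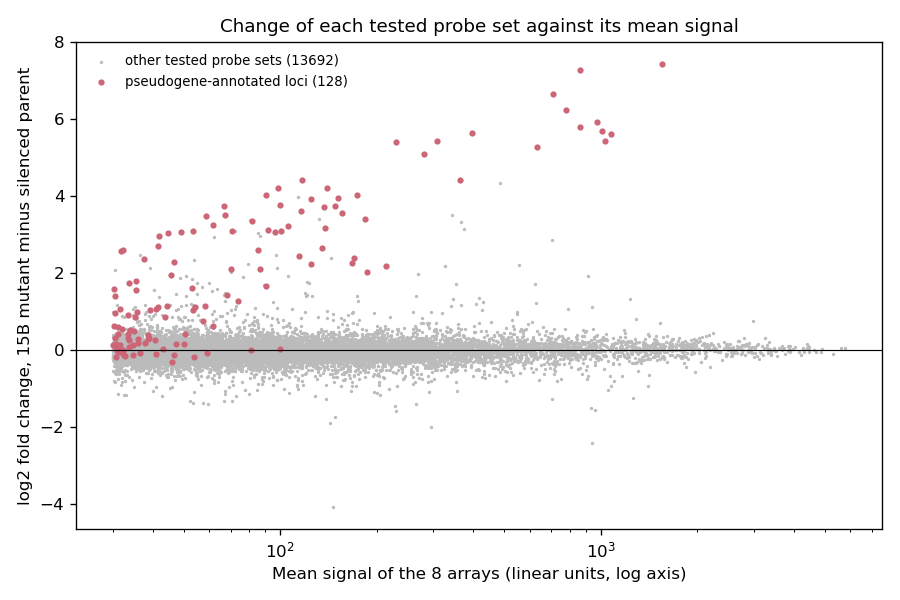
Each point is a tested probe set, with its mean signal over the 8 arrays in linear units on a log axis and its log2 fold change, 15B minus silenced parent. Red points, the 128 probe sets of pseudogene-annotated loci, lie mostly above 0 with a median of 1.56, and the other tested probe sets (grey) lie around 0.

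Pseudogene-annotated loci were frequent among the rises. Of 128 tested probe sets, 84 rose, 76 of them by at least 2-fold, and 0 fell. In the class 90 had an unadjusted p under the threshold. Their median log2 fold change was 1.56 (quartiles 0.29 and 3.26), and 113 of the 128 were positive. The median was 0.45 for _at, 3.08 for _s_at and 3.32 for _x_at probe sets. They made up 84 of the 234 risen probe sets with a known biotype (35.9%) and 44 of the 7193 others (0.612%), an odds ratio of 90.6 (95% interval 59.9 to 139, Fisher's exact test, p = 8.04e-100). This test counts probe sets as independent, although those of near-identical copies can share signal, so the interval may be too narrow. The filter rests on the mean over all 8 arrays, so dim loci could enter through their rise, and the odds ratio was 18.8 with no filter (14.7 to 24.1), 1061 with the higher filter (lower bound 274) and 36.9 in a fit of _at probe sets alone (21.8 to 61.8). Among 255 fallen probe sets there were 0 (p = 0.0234, Fisher's exact test), a result that did not pass with median centring (p = 0.0527). It also did not pass without replicate 2 or 3 of the silenced parent or without any 1 array of 15B (Fisher's exact p up to 0.179). The median silenced parent signal of the tested members was 23.8, under the filter level. Many thus passed the filter through their rise and had little room to fall, so the 0 falls add little. Over all 923 probe sets of the class, below the filter or not, the mean signal was between 7.97 and 10.1 on the 4 silenced parent arrays and between 41.9 and 46.6 on the 4 arrays of 15B. Bright members carried these means, since the median was 3.40 to 5.30 against 6.90 to 8.30, and 4.33% to 7.91% against 15.2% to 18.0% of the 923 reached the filter level. They held 0.233% to 0.309% of all signal in the silenced parent and 1.25% to 1.37% in 15B. By suffix, 33 of 74 _at, 16 of 18 _s_at and 35 of 36 _x_at probe sets rose, and for the last 2 kinds the signal cannot be assigned to 1 locus. With no filter 160 of 923 rose, with the higher filter 52 of 54, and in a fit of _at probe sets alone 31.

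The leading members differed in their silenced parent signal, from 0.975 for AT1G34530 to 37.5 for AT2G10640 on average. AT2G12980 went from 1.1 ± 0.69 to 1719 ± 156 (log2 fold change 7.28, SE 0.09, adjusted p = 7.13e-14 by limma). AT1G43840, measured by an _at probe set, went from 4.20 ± 3.01 to 1420 ± 291 (6.66, SE 0.17). The other 9 were AT2G13870, AT1G33130, AT2G12300, AT3G30396, AT3G31955, AT2G12240, AT4G05640, AT2G10640 and AT1G34530. Their log2 fold changes lay between 5.41 and 6.24, between 5.72 and 7.89 with a pseudocount of 1 and between 3.97 and 5.25 with 30. Sizes and order thus depend on the pseudocount. With a pseudocount of 1 AT2G12980 led and 8 of these 12 were among the 12 largest rises, all 12 of which were again of this biotype. AT4G05640 and AT1G34530 are also measured by _at probe sets, at 4.73 ± 4.07 against 611 ± 25.1 and 0.975 ± 0.492 against 458 ± 40.9. The remaining ones of the 12 are measured by _s_at or _x_at probe sets, whose signal cannot be assigned to 1 locus.

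**Figure D2:**
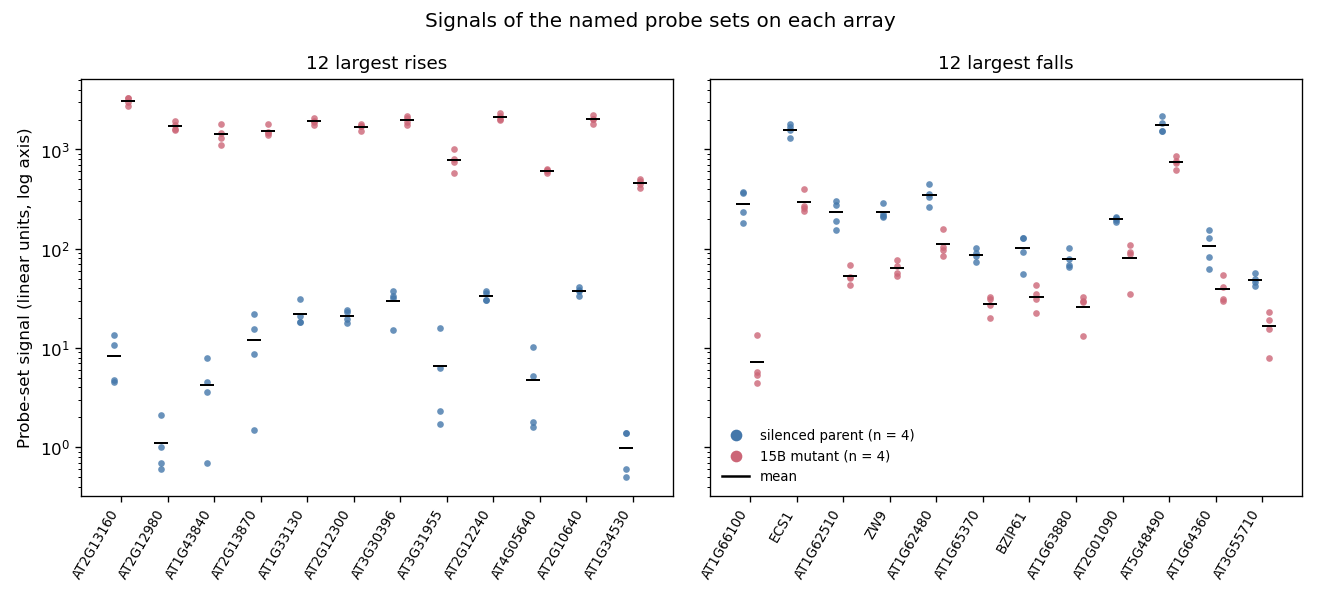
Points are the signals of single arrays in linear units on a log axis, 4 of the silenced parent (blue) and 4 of 15B (red), and black lines are group means. The left panel shows the 12 largest rises and the right panel the 12 largest falls, with no overlap between groups in any of the 24 probe sets.

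Loci that report low DNA methylation had been listed in advance, and all 3 with a tested probe set rose (also adjusted over the list alone). AT2G04770, a CACTA-type DNA transposon locus, went from 22.4 ± 1.49 to 1247 ± 59.1 (log2 fold change 5.28, SE 0.08). QQS went from 195 ± 46.5 to 914 ± 79.8 (2.2, SE 0.14, adjusted p = 4.98e-07 by limma). AT4G08680, a Mutator-type transposon locus, went from 17.1 ± 3.38 to 46.4 ± 7.40 (1.06, SE 0.15). AT2G04770 is measured by an _x_at and AT4G08680 by an _s_at probe set, whose signal cannot be assigned to 1 locus. The 4 other loci of the list, FWA and SDC among them, were not analysed here.

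Around the centromeres, where transposons are dense, rises were more frequent. Of 234 risen probe sets, 86 (36.8%) belonged to pericentromeric genes, against 607 of 7124 others (8.52%, odds ratio 6.24, 95% interval 4.66 to 8.30, Fisher's exact test, p = 3.66e-31). Fallen probe sets had 22 of 255 there (8.63%, odds ratio 0.905, Fisher's exact p = 0.744). Among protein-coding genes alone the share was 19 of 149 risen against 578 of 7073 others (12.8% and 8.17%, Fisher's exact p = 0.0504), which did not pass. Over all probe sets outside the pseudogene biotype, 20 of 601 pericentromeric and 130 of 6629 other ones rose (Fisher's exact p = 0.0346), which passed. These add 1 risen probe set, annotated as a transcribed pseudogene, to the protein-coding ones, so the pass rests on it. Of pseudogene-annotated probe sets, 66 of 92 pericentromeric and 18 of 36 other ones rose (Fisher's exact p = 0.0240). Dim members could pass the filter through their rise, and this comparison was not run with no filter. As a list, the 693 tested pericentromeric probe sets shifted up (camera adjusted p = 5.28e-04, adjusted p = 0.00688 with an estimated correlation), with a mean log2 fold change of 0.30 and a median of -0.01, so mean and median differ in sign. Of its members 86 rose, 22 fell and 585 did not pass, and adjusted over the list alone 91 rose and 41 fell. With no filter the list mean was 0.17 (camera adjusted p = 4.41e-04). With _at probe sets alone the list mean was 0.09 and the camera adjusted p = 0.173.

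Flavonoid synthesis genes, most of which act after CHS in the pathway, rose in part. Of 7 tested probe sets 3 rose, 0 fell and 4 did not pass, and 4 rose adjusted over the list alone. DFR, dihydroflavonol reductase, went from 59.7 ± 18.7 to 180 ± 29.8 (log2 fold change 1.47, SE 0.17, adjusted p = 1.82e-04 by limma). The anthocyanin glycosyltransferases UF3GT (31.7 ± 3.77 to 74.9 ± 17, 1.01, SE 0.14) and AT4G14090 (19.8 ± 11.3 to 90.4 ± 45.9, 1.74, SE 0.30) rose with it, the latter with 1 array of 15B at 159. Values that did not pass were 0.46 for CHIL, 0.34 for AT1G06000, 0.04 for UGT78D2 and 0.03 for UGT78D1, the last pair being flavonoid glycosyltransferases. The list median was 0.46 (camera adjusted p = 5.14e-05), and the call is lost at adjusted p = 0.0918 with an estimated correlation. With fry the call was kept (fry adjusted p = 0.0128). CHS itself was not analysed here.

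Falls were led by protein-coding genes. After AT1G66100 (log2 fold change -4.07, SE 0.22, adjusted p = 8.18e-08 by limma) came ECS1, a cell wall protein gene, from 1585 ± 215 to 292 ± 73.9 (-2.42, SE 0.15). AT1G62510 (-1.89), ZW9 (-1.73), AT1G62480 (-1.59), AT1G65370 (-1.37), the transcription factor gene BZIP61 (-1.34) and AT1G63880 (-1.32) followed. AT2G01090 (-1.27), AT5G48490 (-1.25), AT1G64360 (-1.21) and AT3G55710 (-1.18) completed the 12, of which 8 lie on chromosome 1. Of the cold and drought list 2 of 3 tested members fell and 3 fell adjusted over the list alone. COR47, a dehydrin, went from 931 ± 173 to 525 ± 73.0 (-0.81, SE 0.13) and COR15A from 134 ± 16.2 to 78.7 ± 18.6 (-0.71, SE 0.14), and COR15B was at -0.50 without passing.

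The glucosinolate list had 1 of 4 tested members past the threshold, BCAT4, an enzyme of methionine chain elongation (0.34, SE 0.08, limma adjusted p = 0.0293). This call was lost with quantile normalization (adjusted p = 0.0517, from 0.0222 to 0.0918 over all alternatives). It was also lost without replicate 2 or 3 of the silenced parent and without replicate 1, 2 or 4 of 15B (limma adjusted p from 0.0581 to 0.0918). None of the 3 tested defence probe sets passed over all genes (0, with 3 at an unadjusted p under the threshold), and 3 were higher adjusted over the list alone. PDF1.2b was at 1.12 (SE 0.32, limma adjusted p = 0.0557), PDF1.2 at 1.15 (SE 0.42, adjusted p = 0.127) and THI2.1 at 0.48, the first pair being plant defensins. PDF1.2b is measured by an _x_at probe set, whose signal cannot be assigned to 1 locus, so the pair may not be separate members. PDF1.2b passed without replicate 1 or 3 of the silenced parent, without replicate 3 of 15B and with the replicate number as a block. In these its limma adjusted p was 0.0303 to 0.0382, and it was up to 0.188 over all alternatives. In the methyl cycle list 0 of 4 passed by limma, 1 at an unadjusted p under the threshold, and 1 was higher adjusted over the list alone (MGL 0.44, MMT 0.11). In the phenylpropanoid list 0 of 2 passed, 1 at an unadjusted p under the threshold, and 1 was higher adjusted over the list alone (HCT 0.18, ALDH2C4 0.12).

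Markers of tissue makeup and of growth showed no change past the threshold, but few were tested. These were 1 of 19 photosynthesis, 2 of 13 root and 1 of 17 cell division loci, so organ shares stay largely unchecked. Log2 fold changes were -0.06 for LHCB4.1, a light-harvesting protein of leaves, 0.08 for EXPA18 and -0.09 for EXPA7, expansins of root hairs, and -0.13 for PRL, a DNA replication licensing factor. GI, a clock gene, was at 0.01, the gene SE (SERRATE), which acts in microRNA processing, at 0.27, and the DNA demethylase gene DME, with 3 probe sets, at -0.21, -0.15 and -0.13, with replicate 4 of 15B apart from its group for 1 of these. For these 9 values limma gave 0 calls, and 0 had an unadjusted p under the threshold. The flavonoid regulator, flower, seed, flowering time, heat shock, cytokinin and senescence lists had 0 tested members.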

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

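The test of probe sets shared by near-identical copies and the class of pseudogene-annotated loci were chosen only after the result was seen.

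Single arrays stood apart from the other 3 of their group in 6 of 128 sets of 4 values examined, and chance does this in about 1 in 20. Replicate 4 of the silenced parent had a scanner background of 198 against 77.6 to 94.3 in the other replicates, and a noise of 13.5 against 3.91 to 5.15. Without it 859 probe sets changed and 90 pseudogene-annotated ones rose. Replicate 2 of 15B had 1353 outlier cells against 403 to 505, and without it 588 probe sets changed and 76 pseudogene-annotated ones rose. Among named genes in 15B, AT4G14090 was at 159 in replicate 1 against 64.7 to 72.9. AT1G66100 was at 13.5 in replicate 4 against 4.40 to 5.70, and 1 DME probe set was at 72.9 in replicate 4 against 54.0 to 57.0.

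The rise of pseudogene-annotated loci can be set against shared probes and a general rise of dim signals. Only 1 of the 35 splits of the 8 arrays, the real one, gave as many changed probe sets (920, highest other split 0). Every other split mixes the lines, and the line difference then widens the spread within groups, so the splits cannot exclude chance. The 84 pseudogene-annotated ones moving the same way (highest other 0) add no separate test. They are part of this count and of a class chosen after the rise was seen. Among _at probe sets the odds ratio for these loci was 39.4 with a lower bound of 23.4, and 10.8 with no filter (lower bound 7.97), which argues against shared probes as the whole source, but for the 51 risen probe sets with other suffixes the copy that gave the signal cannot be told apart without values per probe. Background, or DNA carried over into the RNA, would also raise silent protein-coding genes, and of those matched on silenced parent signal 1.06% rose against 160 of 923 of the class with no filter, although multicopy families were not tested apart. The labels separate the groups by line, and a loss of transposon silencing in 15B may be the biological source, a hypothesis the biotype cannot test, since it does not tell transposon genes from other pseudogenes.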

How the results depend on the processing

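Restricting the analysis to _at probe sets and all results on pseudogene-annotated loci as a class were chosen after seeing the data. The count of 920 changed probe sets stayed within 1.5 times under the other scalings, pseudocounts, filters and variance models (788 to 932) and with array weights (1224). It was 191 with a 2-fold limit (156 higher, 35 lower), 392 at an adjusted p under 0.01 (231 and 161) and 502 among probe sets naming 1 gene (238 and 264), since fewer can pass. Leaving out each array gave 523 to 993 in total, 291 to 452 higher and 232 to 541 lower, with fewer samples. With the replicate number as a block (replicate block) 1078 changed (510 higher, 568 lower). Residuals of same-numbered arrays correlated at 0.25, -0.01, 0.05 and 0.05. The best partner was the same number for replicates 1, 3 and 4, so a pairing by number is neither shown nor excluded.

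Of 2 shifted lists 1 was left with an estimated correlation (flavonoid median 0.46, camera adjusted p = 0.0918) and 1 with only _at probe sets (pericentromeric mean 0.0901, camera adjusted p = 0.173). Each list kept its call with fry (fry adjusted p = 0.0128 for flavonoid synthesis and 2.46e-06 for pericentromeric genes). Pseudogene-annotated loci rose in 160 probe sets with no filter, 52 with the higher filter and 31 with only _at, and in 76 to 91 without each array. Their share among falls stayed 0%, and Fisher's exact p rose to 0.0527 with median centring, 0.177 with the higher filter, 0.180 with only _at and up to 0.179 without single arrays. With no filter Fisher's exact p was 1.25e-06, but dim members have little room to fall. The pericentromeric share of falls turned to above that of other genes without the intensity trend (10.5%) and among probe sets naming 1 gene (9.47%), and ranged from 8.28% to 11.1% without each array; it never passed. The enrichments of risen probe sets passed under every alternative run. Of 40 called named probe sets 39 kept their call under each alternative that tested them, and BCAT4 lost it in 8. Of the 40, 18 lacked a value somewhere, 6 of them with the higher filter and 13 with only _at. PDF1.2b, uncalled, passed in 4, the replicate block among them (limma adjusted p = 0.0353, from 0.0303 to 0.188 over all alternatives). GI turned to -0.0166 with array weights and ranged from -0.0874 to 0.0887 without each array, and EXPA18 from -0.00815 to 0.132. The cause was not tested. A different background correction was not run, and signals near the floor limit the fold changes of dim probe sets.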

Other observations

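Calls by limma in this part come from the planned fit. The groupings, the genes with large rises and the gene-order tests were added after seeing the data. Tests of chromosome 1 clustering and of sequence differences were chosen only after the result was seen. For segment loss and neighbouring loci the bounds were set before that test was run.

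Of 7291 tested probe sets of protein-coding genes 255 fell and 149 rose, and 18 of the falls and 36 of the rises reached 2-fold. Large rises were those of AT4G29200 (36.7 ± 3.98 to 930 ± 58.6, SD, n = 4, log2 fold change 4.34), AT1G59930 (3.99), AT1G36240 (3.51), AT5G01080 (3.41), AT2G15560 (3.31), AT5G15690 (3.08) and AT5G41660 (2.46). AT1G59930 is measured by an _x_at and AT5G15690 by an _s_at probe set, whose signal cannot be assigned to 1 locus. Their order depends on the pseudocount, since with 1 in place of 10 AT1G59930 was at 5.35 and AT4G29200 at 4.63. The 69 tested probe sets of chloroplast-encoded genes gave 0 calls by limma, with 4 at an unadjusted p under the threshold. None of 20 families formed from gene symbols shifted (lowest camera adjusted p = 0.83). Among unnamed probe sets 186 rose and 220 fell, 40 and 15 of them by at least 2-fold.

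Of the 12 largest falls among probe sets naming 1 gene, 8 lie on chromosome 1. In a gene-order scan the densest window of 50 neighbouring genes held 9 falls, against a median maximum of 7 over 10000 permutations (p = 0.0453), too near the threshold to exclude chance. Between AT1G56720 and AT1G66100, 29 of 177 tested protein-coding genes fell (16.4%) and 2 rose, but the segment was bounded by its own falls, so this share describes it and tests nothing. The median log2 fold change over all its tested genes was -0.11, which argues against loss of the whole segment in 15B. A stretch of different sequence between the lines, which could weaken hybridisation or change expression, cannot be told apart from linked regulation without values per probe.

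A hypothesis was that protein-coding genes rose where they neighbour pseudogene-annotated loci. Of 147 risen genes, 23 (15.6%) had such a locus among the 2 neighbours on either side in TAIR10.1 gene order, against 691 of 7021 others (9.84%). The odds ratio was 1.70 (95% interval 1.03 to 2.69, Fisher's exact test, p = 0.0255), so the values are in line with it, with a lower bound close to 1. Rises of at least 2-fold gave 2.60 (1.02 to 5.88), from 8 of 36 genes, again with a lower bound close to 1. Fallen genes gave 1.37 (0.910 to 2.00), and rises outside the pericentromeres 1.72 (0.855 to 3.15), both with intervals that hold 1. The difference between risen and fallen genes was not tested, and location around the centromere may account for part.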
